A study of Mus musculus with 2 samples.

How the data were processed

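CTCF is a zinc-finger protein that binds DNA and, with cohesin, anchors chromatin loops. Its binding was measured by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in mouse thymocytes of the CD4+CD8+ (double-positive) stage. The labels list 2 libraries, 1 made with an anti-CTCF antibody and 1 of input DNA. Only the deposited positions of the CTCF library were analysed here. The input library was not analysed here.

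Reads were aligned with Bowtie to mm9, per the submitters' processing notes. The Bowtie version, the peak caller, its threshold and any use of the input library are not given in the sources used here. The deposited file lists 912174 windows of 25 bp that the authors placed in peaks, each as a chromosome, a start and an end. It has no height, read count, score or p-value, so the sequencing depth is unknown and no value per peak can be given. Starts were read as counted from 0, as in a browser track of this kind, and coordinates are printed counted from 1. No window was repeated and 0 had another length. On 10 of 20 chromosomes the last window lay past the last gene of the GRCm38 gene table. Chromosome lengths of GRCm38 were not compared. The build is taken from the submitters' processing notes, and no other GRCm38 coordinate was set against those of the file.

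Adjoining windows (a gap of 0 bp) were joined into regions, which gave 51661 regions. The single region on the mitochondrial genome was left out, and 51660 regions on the 19 autosomes and the X remained. The width of a region was used in place of a peak height, since the plan fixed before the data were examined had assumed a value per peak. The planned use of a mean instead of a maximum height, the share of regions at promoters, the CTCF motif search and the tests of gene lists were not run, because they need a peak value, or a genome sequence or annotation of mm9, which were not used here.

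Regions per Mb were computed for each chromosome up to its last listed coordinate, with exact 95% Poisson intervals. With 1 library these intervals cover counting error only. They treat regions as independent and say nothing of the spread between mice.

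The loci named in the text are 20 windows in mm9, fixed before the data were examined with rounded bounds from general knowledge of where each locus lies. They are 6 antigen receptor loci, 6 loci known for CTCF binding, 7 thymocyte genes and Myc. No mm9 annotation was used to check these bounds, so a region is placed in a window and not assigned to a gene, exon or promoter. A region belonged to a window if its midpoint did. Its number of regions and covered bases were set against 10000 random windows of the same length on the autosomes and the X. A percentile is the share of random windows with a lower value plus the tied share divided by 2. The median width in each window was set against 10000 random draws of as many regions from the genome. These percentiles describe this library and are not p-values. Values above the 95th or under the 5th percentile were called high or low. A low call in the number of regions was possible only for Tcra/Tcrd, Igh and Igk, since in the other 17 windows even an empty window would lie above the 5th percentile. In each antigen receptor window the 5 widest regions were to be given by position, and outside the windows the 10 widest of the genome.

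Distances between neighbouring regions were compared with 100 random placements of the same number of regions on each chromosome. Random placements were not joined where they fell close together. The gene table (RefSeq, GRCm38) was used for the number of genes per chromosome, the position of the last gene on each (compared as above), the number of V segments per locus (pseudogenes included) and the order of V segments and constant genes.

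The window step was tested on simulated data with 55068 regions and 50 windows of 1 Mb per setting. Of windows made 4 times denser, 94% came out above the 95th percentile, of windows made 2 times denser 62%, and of unchanged windows 2%. Of windows thinned to 0.25 of their density, 86% came out under the 5th percentile. These regions were placed at random along each chromosome, so the shares do not carry over to the real library, in which 12.2% of 1-Mb bins were empty. An empty 1-Mb window would lie at percentile 6.1 there, so the test does not show that thinned windows of the real library are called low. The alternatives were the wider 50% and the widest 25% of regions, taken as those of at least the median (525 bp) and the upper quartile (625 bp), which with ties held 51.8% and 29.9% of regions, joining regions at most 100, 500 or 1000 bp apart, leaving out regions of at most 75 bp, and random windows or regions from the same chromosome. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.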

Results

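CTCF-bound regions were mapped in 1 ChIP-seq library of thymocytes from C57BL/6 mice of 4 to 8 weeks. The mice lacked Rag1, a recombinase needed to assemble antigen receptor genes, and carried an already rearranged T cell receptor beta transgene. With Rag1 absent, the endogenous receptor loci of these cells stay unrearranged. Chromatin had been fixed with 1% formaldehyde for 10 minutes. With 1 CTCF library there was no replicate, and every comparison is between parts of the genome in that library. The series set out to locate CTCF sites in lymphocyte subsets, so the antigen receptor loci were examined beside other loci.

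The library held 51660 CTCF regions on the autosomes and the X, which covered 22.8 Mb, or 0.865% of the chromosomes up to their last listed positions. This corresponded to 19.6 regions per Mb. The median width was 525 bp, and the mean was 441 bp (SD 251 bp across regions). The most frequent width was 625 bp, shared by 4911 regions, and 35.3% of regions were 575 to 675 bp wide. A smaller mode lay at 325 bp with 2025 regions. Regions of at most 75 bp numbered 7300 (14.1%), and 59.5% of these had another region within 200 bp, compared with 11.2% of the other regions. Regions wider than 1 kb numbered 538 (1.04%). Outside the fixed windows, the widest region was 4075 bp on chromosome 17 (39979777 to 39983851), followed by 2550 bp on chromosome 5 (124560946 to 124563495) and 2325 bp on chromosome 1 (88396346 to 88398670). The other 7 of the 10 widest regions were 1750 to 2100 bp wide and lay on chromosomes 13, 4, 5, 8, 2, 2 and 10. A further 4 regions, on chromosomes 18, 18, 19 and 5, tied with the last at 1750 bp. Whether reads of the input library also piled up in these widest regions was not examined.

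**Figure D1:**
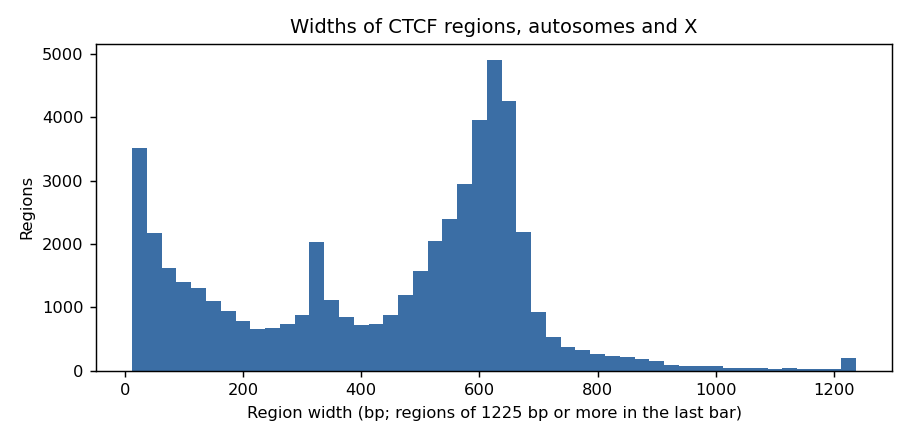
Histogram of region widths in bp (horizontal axis) against the number of regions (vertical axis) for the 51660 regions on the autosomes and the X. The main mode lies at 625 bp, a smaller one at 325 bp, and 3514 regions are a single 25-bp window.

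The X carried fewer CTCF regions than any autosome. It held 7.65 regions per Mb (95% Poisson interval 7.24 to 8.09, 1274 regions), whereas the autosomes together held 20.4 per Mb, a ratio of 0.375. Among regions of at least 525 bp the ratio was 0.362. It was 0.240 among regions of at least 625 bp, a bound applied to the X after the data were seen that equals the most frequent width. Chromosome 11 was the densest with 33.4 per Mb (32.4 to 34.5), followed by chromosome 19 with 25.8 (24.5 to 27.1) and chromosome 17 with 25.4 (24.4 to 26.5). The sparsest autosome was chromosome 3 with 14.8 per Mb (14.2 to 15.4). The intervals of the X and of chromosome 3 did not overlap. Of the chromosome length, 39.95% of the X lay in gaps of over 1 Mb between neighbouring regions, compared with 12.7% to 28.9% of each autosome. No region was listed on the Y.

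**Figure D2:**
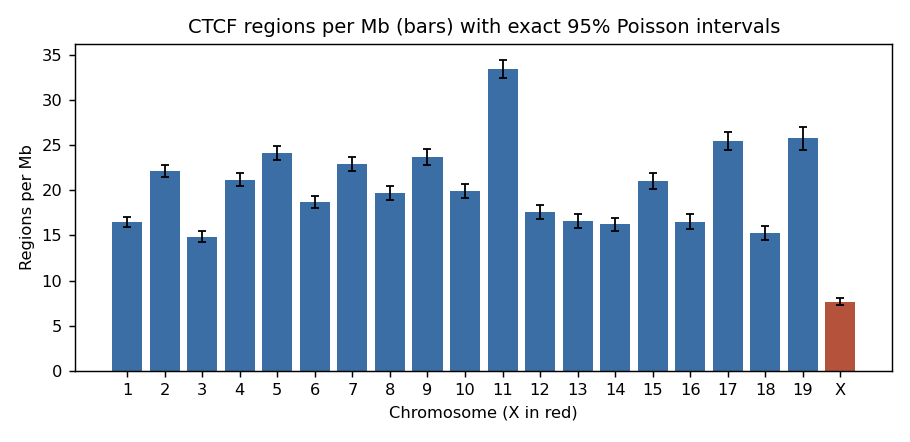
Regions per Mb (vertical axis) on each chromosome (horizontal axis), with exact 95% Poisson intervals as error bars and the X in red. Chromosome 11 is highest at 33.4 per Mb and the X lowest at 7.65 per Mb.

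Among the antigen receptor loci, Tcra/Tcrd stood apart in its number of CTCF regions. This window on chromosome 14, which holds the genes of the T cell receptor alpha and delta chains, contained 188 regions, 98.9 per Mb (95% Poisson interval 85.3 to 114), against a median of 29 in random windows of its length. It lay at the 99.9th percentile, and covered bases gave the same percentile. In this window 18 pairs of regions lay 310.9 to 311.1 kb apart, as described below, so its 188 regions may not all be independent sites. Igh, the immunoglobulin heavy chain locus on chromosome 12, held 148 regions, 51.0 per Mb (43.1 to 59.95), with a random median of 46. It was at the 93.3rd percentile for the number of regions, under the threshold, and at the 95.5th for covered bases. In each of the 5 alternative settings for windows its number of regions was above the threshold (95.01st to 97.17th percentile), and its covered bases were at the 94.3rd percentile after joining regions at most 1000 bp apart. Tcrb held 32 regions and Tcrg 13, at the 83.2nd and 83.7th percentiles. Of the immunoglobulin light chain loci, Igk held 17 regions, 5.31 per Mb (3.09 to 8.51), against a random median of 51 (20.02nd percentile, not called low), and Igl held 4 against a random median of 3 (54.4th). The intervals per Mb of Tcra/Tcrd and Igh, which cover counting error only and not the spread between genomic windows, overlapped neither each other nor that of Igk. The wide random spread kept Igk above the 5th percentile, since random windows of its length ran from 2 (5th percentile) to 178 (95th percentile) regions.

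Tcra/Tcrd and Igh also had a higher median width than the genome. It was 600 bp in both, against 525 bp, above all 10000 random draws for Tcra/Tcrd and at the 99.98th percentile for Igh. Xist, Cd3e/d/g and Myc had the same median with 8, 7 and 4 regions, at the 85.9th, 81.5th and 81.3rd percentiles. The percentile thus depends on the number of regions in a window, and the draws took neighbouring regions as independent. In Tcrb the median width was 562.5 bp (78.8th percentile), in Tcrg 525 bp (50.4th), in Igk 400 bp (17.9th) and in Igl 325 bp (20.2nd). Set against the V segments listed for each locus, there were 1.38 regions per V segment in Tcra/Tcrd (136 V segments), 0.809 in Igh (183), 0.914 in Tcrb (35), 1.86 in Tcrg (7), 1.33 in Igl (3) and 0.105 in Igk (162). These ratios count every region of a window, wherever it lies and however short, so their order depends on how regions are joined. After joining regions at most 1000 bp apart, the windows held 157, 137, 31, 9, 2 and 13 regions in the same order.

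Within Tcra/Tcrd the regions were most frequent in the middle of the window. In the GRCm38 gene order all 130 Trav segments lie at lower coordinates than Trac, the alpha chain constant gene. Split into 4 equal parts from low to high coordinates, the window held 31, 66, 66 and 25 regions. The median distance between neighbouring regions was 6.125 kb, and the longest gap was 58.6 kb. The 5 widest regions were 1275 bp (54329170 to 54330444), 1200 bp (53626870 to 53628069), 1200 bp (53938045 to 53939244), 1125 bp (53441095 to 53442219) and 1125 bp (54136095 to 54137219). Their surroundings recurred. The region of 1275 bp and both of 1200 bp each came after a region of 550 or 625 bp at nearly the same distance. Both regions of 1125 bp were followed by regions of 625 and 50 bp, as was one of 1100 bp from 53751895. These 5 regions may therefore not all be independent sites, as described below for the repeated arrangement of the window.

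Igh combined regions along most of its length with a compact group at one end. Its 4 equal parts held 30, 37, 39 and 42 regions, with a median distance of 15.0 kb. At its low-coordinate end, where Igha, a constant gene, lies ahead of all 183 Ighv segments in the gene order, 6 regions within 10 kb (114453961 to 114462885) covered 5875 bp. By covered bases this was rank 1 among the 51660 stretches of 10 kb that start at a region, with regions at their far end counted whole, a measure added after the data were examined. The 3 widest regions of the window were in this group, at 1375 bp (114460061 to 114461435), 1275 bp (114457911 to 114459185) and 1250 bp (114455336 to 114456585). The other 2 of the 5 widest were 850 bp (from 115219711) and 775 bp (from 114849011, tied with 1 from 115286061). The longest gap of the window, 260 kb from 114462886 to 114723160, followed directly.

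In Tcrb, a gap of 223.75 kb (41231446 to 41455195) separated 2 sets of regions. Its 5 widest regions were 675 bp (from 41062696, 41137771 and 41554121) or 650 bp (from 41058746 and 41455196), with a region of equal width, from 41572471, not among the 5. The samples carried a beta chain transgene, and whether reads from it were placed in this window is not recorded in the labels. In Tcrg, 6 of the 13 regions lay together at the high-coordinate end, 19454096 to 19457945, including 2 of 675 bp, and the other 3 of the 5 widest were 650 bp (from 19225571, 19250221 and 19269296). The 6 included short regions of 50, 75 and 25 bp (from 19456971, 19457046 and 19457146). After joining regions at most 1000 bp apart, the Tcrg window held 9 regions. In Igk, no region was listed over 1478.2 kb, from 68618871 to 70097070. At its high-coordinate end, where Igkc lies after all 162 Igkv segments, 5 regions (70659146 to 70664695) covered 2075 bp, and 3 of the 5 widest regions of the window, at 650, 625 and 625 bp, were among them. The remaining 2 were 625 bp (from 67648821) and 575 bp (from 68618296). In Igl, 2 regions were wider than 25 bp, at 825 bp (from 19002728) and 625 bp (from 19146553), and the other 2 were 25 bp wide.

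**Figure D3:**
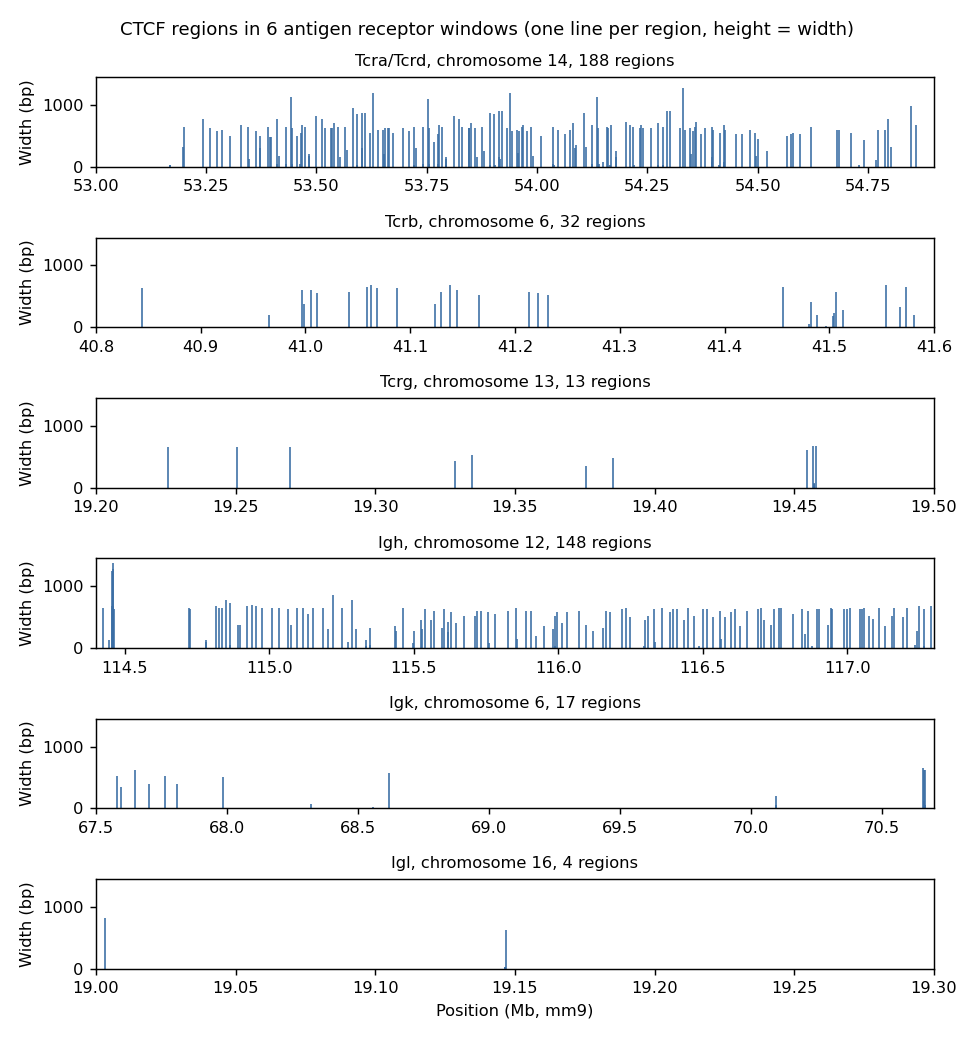
Position in Mb of mm9 (horizontal axis) and width in bp (vertical axis) of each CTCF region, 1 line per region, in the 6 antigen receptor windows. Tcra/Tcrd (188 regions) and Igh (148 regions) are filled along most of their length, Igk shows an empty stretch of 1478.2 kb, and the tallest line, 1375 bp, is in the group at the low-coordinate end of Igh.

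Around genes used by thymocytes, 3 of 7 windows were above the 95th percentile for the number of regions. Windows this short could not come out low. Cd4, which encodes a T cell co-receptor, had 10 regions in its window (99.6th percentile), among them 1 of 1150 bp (124853421 to 124854570). Rag1/Rag2, the pair of recombinase genes, had 11 (99.3rd), and Cd8a/Cd8b1, the genes of the other co-receptor, had 11 (98.4th). Median widths in these 3 windows were 387.5, 325 and 425 bp (20.3rd, 10.8th and 25.1st percentiles). The mice lacked Rag1, and how the altered allele bears on reads in the Rag1/Rag2 window was not examined. Bcl11b, a transcription factor of the T lineage, had 14 regions (94.1st) and Cd3e/d/g, which encode signalling chains of the T cell receptor complex, had 7 (92.7th number, 95.7th covered bases). Runx1 with 13 regions (83.9th) and Ets1 with 5 (75.6th) were inside the random range. Myc, the window that belongs to no lineage list, had 4 (80.6th). Among regions of at least 625 bp, the percentile of Cd8a/Cd8b1 was 94.0, under the threshold. For Cd3e/d/g, covered bases were under the threshold in 3 of 5 alternative settings (92.5 to 94.9) and the number of regions was above it in 3 (95.3 to 96.1). The number of regions of Bcl11b was above it against windows of its own chromosome (96.9). Random windows were not matched on genes, and the Poisson intervals of these short windows were wide, for example 4.80 to 18.4 regions for Cd4.

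Of the 6 loci known for CTCF binding, none passed the 95th percentile in number, and Xist, the non-coding RNA of X inactivation, passed it in covered bases. Xist had 8 regions (94.99th percentile, 97.2nd for covered bases), and its number was above the threshold in each of the 5 alternative settings (97.1st to 99.6th). H19/Igf2, an imprinted pair of genes, had 10 regions (86.8th number, 94.0th covered bases, and 95.9th and 97.2nd among regions of at least 625 bp), and its widest was 1000 bp (149765955 to 149766954) with a neighbour of 775 bp at a distance of 450 bp (149767405 to 149768179). Hoxd with 9 regions (84.5th), Hoxa with 8 (81.0th) and Hbb, the beta-globin locus, with 6 (72.7th) were inside the random range. H19/Igf2 and Hoxa had high median widths, 625 bp in both (96.2nd and 95.1st percentiles), the former at the 93.97th percentile against regions of its own chromosome. The median width of Xist was at the 85.9th percentile, and at the 95.2nd against regions of the X. The protocadherin window Pcdha/b/g, a cluster of cell adhesion genes, went the other way: its 55 regions (88.3rd percentile in number, 96.4th against windows of its own chromosome) had a median width of 350 bp, at the 1.58th percentile. Of these, 33 lay in the last of its 4 equal parts, and the median distance in the window was 5.725 kb.

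**Figure D4:**
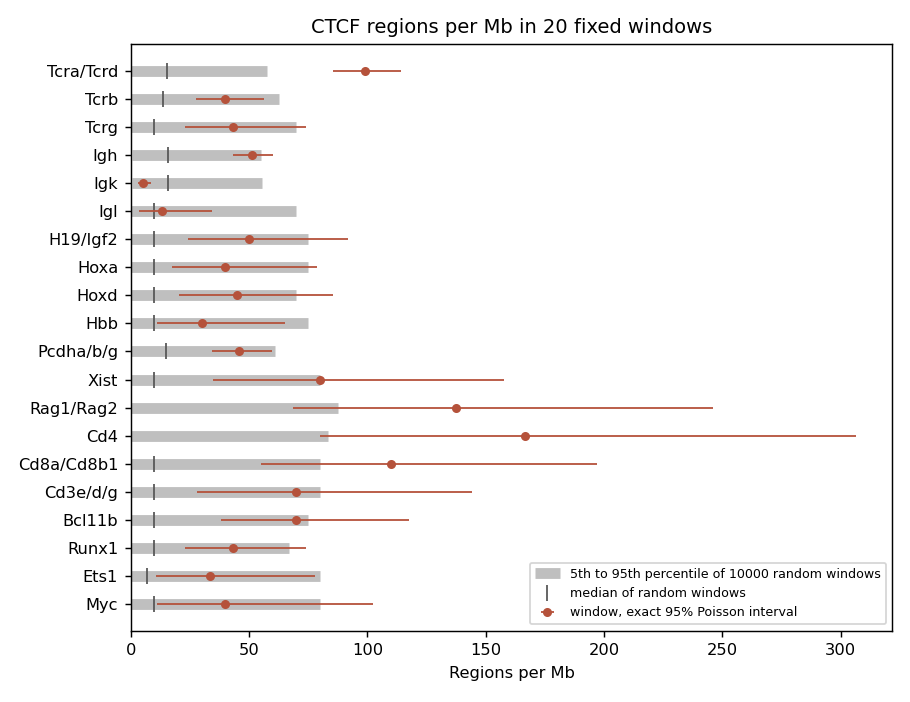
Regions per Mb (horizontal axis) in each of the 20 fixed windows (points, with exact 95% Poisson intervals) beside the 5th to 95th percentile range (grey bars) and median (ticks) of 10000 random windows of the same length. Tcra/Tcrd, Rag1/Rag2, Cd4 and Cd8a/Cd8b1 lie beyond their grey bars, and Igk lies below its random median.

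CTCF regions lay closer together than random placement gave. The median distance between neighbouring regions was 13.1 kb, compared with 32.4 kb in random placements (range of 100 placements 32.1 to 32.7 kb). The lower quartile was 3.325 kb against 13.04 kb, and the upper quartile 36.7 kb against 66.6 kb. The difference was smaller after joining regions at most 1000 bp apart and keeping the number in each 1-Mb bin in the placements. The median was then 17.8 kb against 23.3 kb and the lower quartile 6.95 kb against 8.7 kb. Counted in bins of 1 Mb, the median was 14 regions, 315 of 2582 bins held none, and the highest number was 120, reached in 2 neighbouring bins of chromosome 10 (79000001 to 81000000). The first Mb of the Tcra/Tcrd window, 53000001 to 54000000 on chromosome 14, ranked 7 with 105 regions. The longest stretch without a region, 14.2 Mb, was on the X (111672236 to 125838360).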

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

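The settings that joined regions at most 100 bp apart, left out regions of at most 75 bp or kept the number of regions in each 1-Mb bin were chosen after seeing the data, as was applying settings other than the bound of 525 bp to the X. Keeping regions of at least the median width (525 bp) or the upper quartile (625 bp) left 26765 (51.8%) and 15427 (29.9%) regions, shares set by these bounds and by ties at them, while joining regions or leaving out short ones gave 43881 to 47421 regions and a median width at most 50 bp above the 525 bp of the unjoined regions. The ratio of X to autosome density was 0.240 among regions of at least 625 bp and 0.397 after joining at 1000 bp, and 0.362 to 0.392 in the other settings. The number of windows above the 95th percentile in number of regions rose from 4 to 7 with regions of at least 525 bp, with joining at 1000 bp and without short regions, and to 8 against random windows of the same chromosome. For covered bases it was 5 to 7 in all settings. Igh and Xist passed the 95th percentile in number under all 5 settings, and Cd3e/d/g, Pcdha/b/g, Bcl11b and H19/Igf2 under 1 to 3, so the count of 4 windows is sensitive to these choices, and the cause was not tested. Cd8a/Cd8b1 was no longer above it among regions of at least 625 bp (94.0), and Cd3e/d/g lost its call in covered bases under 3 settings (92.5 to 94.9). No percentile called high or low moved to the other side of the random median under the settings run for it. For median widths the only setting run was regions of the same chromosome as background. The median distance between regions stayed below the lowest random placement in the 3 settings run for it, at 0.465 of the random value after joining at 1000 bp, 0.684 with the number kept per 1-Mb bin and 0.763 with both. Without heights, counts or depth, neither weak binding nor absence of binding can be read from a position that is not listed.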

Other observations

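The test of recurring distances against chance, the counts of V segments, the covered bases per 10 kb and the correlation with gene number were chosen after the data were examined. The other tests of explanations were set before their results were seen.

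CTCF regions were more frequent on chromosomes with more genes. Across 20 chromosomes, regions per Mb correlated with protein-coding genes per Mb, with Pearson's r = 0.846 (permutation p = 1e-05, adjusted 2e-05) and Spearman's rho = 0.898 (permutation p = 1e-05, adjusted 2e-05), where 1e-05 is the smallest p that 100000 permutations can give. Without chromosomes 7 and 11, the 2 farthest from the median in gene density, r was 0.856. With all listed genes r was 0.769 and rho 0.779, in a family of 2 relations. Chromosome 7, with 13.3 protein-coding genes per Mb, had 22.9 regions per Mb, while chromosome 11, with 13.2, had 33.4. In Pcdha/b/g, 4 regions that start within 10 kb of each other covered 2650 bp in whole (38036832 to 38047131), and in Bcl11b 5 such regions covered 2325 bp (109236836 to 109244885).

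The first pattern is the low density of the X. Fewer genes may account for part of it but did not account for all of it. A line through the 19 autosomes predicted 16.1 regions per Mb from the gene density of the X (95% prediction interval 10.9 to 21.3). The autosomes together had 20.4, and the X had 7.65, under that interval. Fewer reads per X site, from a single X copy in male mice or from poorer mapping, may contribute, if width follows the number of reads, which was not tested. Of X regions, 19.2% (exact 95% interval 17.1% to 21.5%) were at least 625 bp wide, compared with 29.9% of all regions and 27.2% on the lowest autosome. X regions of at least 500 bp had a median width of 600 bp against 625 bp on each autosome, but the median over all X regions, 525 bp, was inside the autosome range of 500 to 550 bp, and regions of at most 75 bp made up 10.5% on the X and 12.1% to 15.6% on the autosomes. The sex of the mice is not in the labels, and no region was listed on the Y, which alone does not give the sex. A difference in copy number and a lower number of CTCF sites on the X therefore remain open, and the biological explanation was not tested.

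The second pattern is the close spacing of regions. Splitting of single sites does not explain it as a whole, since after joining regions at most 1000 bp apart the median distance was 17.8 kb and the lowest of 100 random placements 37.9 kb. Differences between megabases in the number of regions covered a large part of it, and what lies behind these differences was not tested. Keeping the number in each 1-Mb bin lowered the random median for joined regions from 38.3 kb to 23.3 kb. They did not account for all of it, because the lowest of these placements was 23.0 kb against the same 17.8 kb. Clustering at a scale below 1 Mb, for example around genes, and stretches where reads cannot be placed may both contribute, and neither was tested. No group in the design gives a biological explanation to test.

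The third pattern is a repeated arrangement of regions in the Tcra/Tcrd window. Among its 159 regions of at least 100 bp, 18 pairs lay 310.9 to 311.1 kb apart, compared with at most 14 pairs at any 1 distance in 1000 shuffles of the gaps, which argues against chance. Pairs just outside this range, such as the regions of 1200 bp from 53626870 and 53938045, were not counted. The regions of 1100 bp from 53751895 and 1125 bp from 54136095, each followed by one of 625 bp, recurred at another distance. The 18 pairs therefore do not cover every repeated region of the window. Of the 18 pairs, 15 (83.3%, exact 95% interval 58.6% to 96.4%) matched in width within 50 bp, against 25.2% of pairs at other distances. The same search gave at most 7 pairs in Igh, 4 in Pcdha/b/g and 3 in Tcrb, none above its shuffles. A hypothesis is that the regions lie in duplicated blocks of the V array: binding in each copy and reads shared between near-identical copies predict the same match in width, so these cannot be told apart without the sequence and the alignment settings, and the 188 regions of the window could include both.

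On the mitochondrial genome 1 region of 50 bp was listed. The region of 4075 bp on chromosome 17 was 1.6 times as wide as the next widest outside the windows, and with a neighbour it gave 5750 bp in 10 kb, second to the group in Igh. The input library was not analysed, so whether reads also piled up there without the antibody is not known.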
